A study of Mus musculus with 72 samples.

How the data were processed

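Whole-lung RNA of WT and Bmp6 KO mice in air or cigarette smoke was sequenced in 72 libraries, 1 deposited file each. The deposited values are whole-number read counts per Ensembl gene, not normalised, with the gene symbol beside each ID. Per the labels' protocols, total RNA was isolated with the miRNeasy kit, libraries were checked for ribosomal and globin content, and sequencing was on an Illumina NovaSeq instrument. Per the submitters' processing notes, adapters were trimmed with Trimmomatic 0.30, reads were aligned to GRCm39, and DESeq2 1.34.0 was used downstream. The aligner, the counter, the annotation release and the strand setting are not given in the sources used here, so overlapping and antisense genes cannot be told apart, and copies such as Hspa1a and Hspa1b, Hamp and its neighbour copy, or histone genes are uncertain in how they split reads. The model formula of the authors is not given either, and neither are sequencing batches, animal numbers or sex.

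The files held 55414 gene IDs in the same order, 1399 of them without a symbol, and 54749 were found in the GENCODE vM39 annotation of GRCm39, from which coordinates were taken. Groups came from genotype, exposure and time in the labels, and replicate numbers in the text follow the order of deposit and pair nothing. No library pair within a group was identical over 299 pairs. Every library looked male, with at most 0.74 CPM of Xist and 98.3 to 221 CPM of Ddx3y. Total counts per library ran from 3.74 to 42.4 M.

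Counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test with TMM scaling, in 1 model with a mean for each of the 8 groups. The filter (filterByExpr, a count of 10, 7 libraries) kept 17163 genes with 99.91% of counts, and 64 residual degrees of freedom remained. There were 12 contrasts: smoke against air in 4 settings, KO against WT in 4 settings, and 4 differences between such effects. Benjamini-Hochberg adjustment was within each contrast, a call is an adjusted p under 0.05, and the SE of a log2 fold change is its size divided by the square root of F. These p values measure the spread between libraries, and the labels do not say that each library is another mouse. The median log2 fold change of all genes lay close to 0 in each contrast.

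A collection of 41 gene lists of cell types and pathways (653 genes) was tested with fry in limma 3.58.1, two-sided and adjusted over the lists of a contrast. This test asks whether the genes of a list move, on balance, one way, and its mixed form whether they change in either direction, and neither compares a list with other genes. The competitive test camera with an estimated correlation was the alternative. For each list the members called over all genes tested and adjusted over the list alone were counted. The lists come from general knowledge of markers, and some members are expressed by more than 1 cell type.

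The contrasts, lists, first alternatives and the rule for naming genes were fixed before the data were examined, and the alternatives added later are named as such in the closing part. The rule took the 10 highest and 10 lowest log2 fold changes among calls with a mean of at least 1 CPM for smoke in WT mice and for genotype in air, and the 5 highest and 5 lowest in the other contrasts. Predicted models and immunoglobulin or T cell receptor segments were only counted. From each list up to 4 called members with the smallest adjusted p could be named. Some genes within this rule are not reported here. Genes given as libraries' values in the closing part, and the genes named for the smoke by genotype difference at 24 weeks, were chosen later.

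Alternatives were other size factors, other filters, only the groups compared, voom with quality weights, 2 surrogate variables (sva 3.50.0) and DESeq2 1.42.0. The model was tested on simulated counts of all 17163 genes with 200 changed genes. For WT smoke against air at 4 weeks it recovered 70.1% of genes changed 1.5-fold, 94% at 2-fold and 100% at 4-fold, with 5.88% of its calls false. For the genotype by smoke difference at 4 weeks these were 61.2%, 85.1% and 95.5%, with 6.94% false.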

Results

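Gene expression was measured by bulk RNA sequencing in 72 libraries of whole mouse lung. The mice were wild type (WT) or carried a knockout (KO) of Bmp6, which encodes a secreted ligand of the bone morphogenetic protein (BMP) family, and breathed air or cigarette smoke for 4 or 24 weeks. At 4 weeks there were 8 libraries of WT mice in air, 8 of WT mice in smoke, 8 of KO mice in air and 7 of KO mice in smoke. At 24 weeks the same groups held 10, 12, 8 and 11 libraries. Total counts ran from 3.74 to 42.4 M per library (M, mega) with a median of 13.07 M, and 17163 genes were tested. The comparisons asked what smoke changed in each genotype, what loss of Bmp6 changed in each exposure, and whether these effects differed from each other. Fold changes are log2 values ± standard error (SE). Levels are counts scaled to library size (CPM), as mean ± SD over the libraries of a group. Adjusted p values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested.

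The knockout was read first in every group, since it checks the genotype labels. Bmp6 (ENSMUSG00000039004, chromosome 13, 38529065 to 38684280, GRCm39) stood at 214 ± 20.2 (SD, n = 8) CPM in WT mice in air at 4 weeks and at 41.5 ± 9.00 (SD, n = 8) CPM in KO mice in air. In smoke at 4 weeks the levels were 203 ± 28.0 and 32.0 ± 6.25 CPM in WT and KO mice. At 24 weeks they were 223 ± 15.5 and 39.7 ± 9.74 CPM in air, and 204 ± 20.2 and 34.0 ± 3.68 CPM in smoke. The KO to WT log2 fold change was -2.37 ± 0.12, adjusted p = 1.96e-27, in air at 4 weeks. It was -2.67 ± 0.12, adjusted p = 5.2e-29, in smoke at 4 weeks. At 24 weeks it was -2.49 ± 0.11, adjusted p = 1.88e-29, in air and -2.59 ± 0.10, adjusted p = 4.3e-34, in smoke. Which part of the gene the allele lacks was not given, so the transcript left in KO libraries is not known. Bmp6 was lower in smoke in KO mice at 4 weeks (-0.37 ± 0.12, adjusted p = 0.0306), a call lost at -0.35 (adjusted p = 0.0519) without KO air 4 weeks replicate 8, and passed in no other group.

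**Figure D1:**
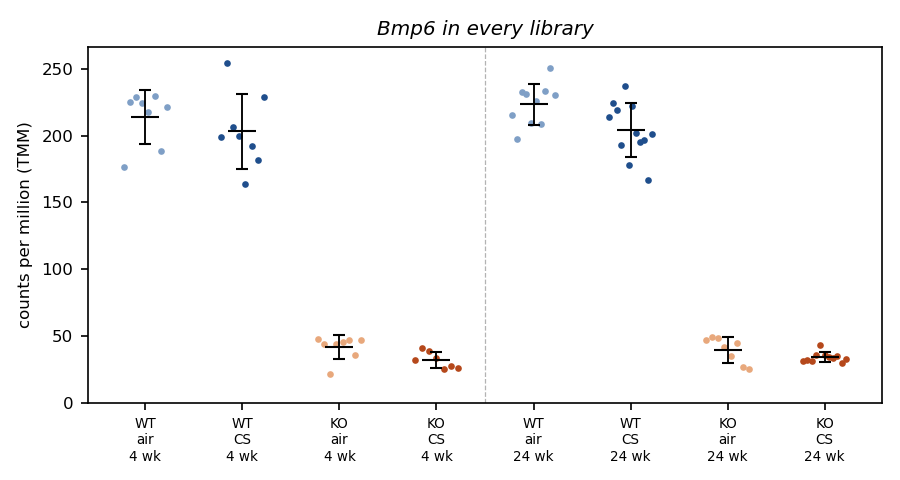
Bmp6 level (normalised CPM, vertical axis) in each library of the 8 groups (horizontal axis), each point a library and bars the mean ± SD. The KO groups had means of 32.0 to 41.5 CPM and the WT groups means of 203 to 223 CPM.

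After 4 weeks of smoke the WT lung had lower heat shock and unfolded protein genes than in air, and many clock genes differed. Of 17163 genes tested, 737 were higher and 808 lower in smoke (1545 in all), 187 of them by more than 2-fold. The gene with the highest fold change was Dbp, a transcription factor driven by the circadian clock (ENSMUSG00000059824, chromosome 7, 45354512 to 45359627). It stood at 3.32 ± 1.01 (SD, n = 8) CPM in air and 99.3 ± 38.9 (SD, n = 8) CPM in smoke (4.97 ± 0.38, adjusted p = 1.45e-16). The clock repressors Nr1d1 (ENSMUSG00000020889, chromosome 11, 98658752 to 98666188; 3.92 ± 0.30, adjusted p = 1.45e-16) and Nr1d2 (3.09 ± 0.21, adjusted p = 2.15e-19) rose with it. Per3, a period gene of the same loop, rose too (2.14 ± 0.17, adjusted p = 6.01e-16). The activators of that loop fell, Npas2 (-2.14 ± 0.24, adjusted p = 4.54e-10) and Arntl, also known as Bmal1 (-1.89 ± 0.19, adjusted p = 1.67e-11). Higher genes of inflammation were Ear6, an eosinophil-type ribonuclease (4.14, adjusted p = 5.92e-05), Saa3, an acute-phase amyloid (2.68, adjusted p = 0.000303), and the chemokine receptor Cxcr1 (2.62, adjusted p = 3.34e-07). The surface protein gene Ly6i (2.44, adjusted p = 0.00135) rose as well. Stra6l, which takes up retinol (2.65, adjusted p = 1.34e-06), and the zinc transporter Slc39a2 (1.94, adjusted p = 1.29e-06) completed the 10 highest.

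The lowest gene in smoke at 4 weeks was Hspa1b, an inducible heat shock protein of the Hsp70 family (ENSMUSG00000090877, chromosome 17, 35175412 to 35178214). It was at 131 ± 52.2 CPM in air and 17.6 ± 12.3 CPM in smoke (-2.88 ± 0.47, adjusted p = 7.49e-06). Its near-identical copy Hspa1a fell too (-2.43 ± 0.42, adjusted p = 3.75e-05), and how reads were split between the copies is not known. Next came the sorting nexin Snx31 (-2.32, adjusted p = 2.21e-05), the epidermal matrix gene Rptn (-2.07, adjusted p = 3.62e-06) and the secreted matrix protein gene Spon2 (-2.06 ± 0.21, adjusted p = 2.34e-11). The histone gene H3c4 (-2.02, adjusted p = 6.98e-05) and the fatty acid hydroxylase gene Cyp4a12b (-1.89, adjusted p = 0.00996) also have close copies. Gdpd2, a glycerophosphodiesterase, completed the lower set (-1.84 ± 0.17, adjusted p = 1.01e-12). Predicted models made up 75 of the higher and 37 of the lower calls, and immunoglobulin or T cell receptor segments 8 and 1.

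Protein folding genes moved one way in WT lung at 4 weeks. Among 20 heat shock and unfolded protein genes, 16 fell over all genes tested and 17 adjusted over the list alone (adjusted p = 6.05e-09, and adjusted p = 0.00517 with an estimated correlation). Hspa8, the constitutive Hsp70 chaperone, dropped from 2384 ± 276 to 1209 ± 239 CPM (-0.98 ± 0.12, adjusted p = 1.39e-08). Its endoplasmic reticulum relative Hspa5 (-0.81 ± 0.10, adjusted p = 1.92e-09), the co-chaperone Hsph1 (-1.57 ± 0.24, adjusted p = 1.59e-06) and the secreted stress factor Manf (-0.77 ± 0.12, adjusted p = 1.78e-06) were lower as well. Of 16 clock genes, 9 rose and 6 fell over all genes tested, 10 and 6 adjusted over the list alone (adjusted p = 6.68e-08, and adjusted p = 0.0556 with an estimated correlation).

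Of 15 B cell genes in WT smoke at 4 weeks, 12 rose over all genes tested and 14 adjusted over the list alone (adjusted p = 0.00157, and adjusted p = 0.207 with an estimated correlation). These included the inhibitory receptor Cd22 (1.03 ± 0.19, adjusted p = 6.29e-05), the IgE receptor Fcer2a (1.37 ± 0.26, adjusted p = 0.000187) and the IgM receptor Fcmr (1.05, adjusted p = 0.00359). T and NK cell (adjusted p = 0.325) and interstitial macrophage lists (adjusted p = 0.812) had no call. Among 10 MHC class II genes, 3 rose over all genes tested and 8 adjusted over the list alone (adjusted p = 0.00171, and adjusted p = 0.207 with an estimated correlation), led by H2-Ob (0.95 ± 0.18, adjusted p = 9.39e-05). Alveolar macrophage genes were higher (9 of 19 rose and 1 fell, 9 and 2 adjusted over the list alone, adjusted p = 0.0257, adjusted p = 0.531 with an estimated correlation). They included the protease Ctsk (1.88 ± 0.27, adjusted p = 6.36e-07) and the scavenger receptor Marco (1.63, adjusted p = 0.000379). Lipid-associated macrophage genes were higher (6 of 19 rose and 0 fell, 10 and 1 adjusted over the list alone, adjusted p = 0.0339, adjusted p = 0.531 with an estimated correlation). They included Gpnmb (1.68 ± 0.25, adjusted p = 1.06e-06) and Trem2 (1.29, adjusted p = 0.000899), which recognises lipids. Dendritic cell genes were higher (3 of 15 rose, 5 adjusted over the list alone, adjusted p = 0.0467, adjusted p = 0.531 with an estimated correlation). They included the chemokines Ccl22 (1.17, adjusted p = 0.00022) and Ccl17 (0.99, adjusted p = 0.00956), and this list had adjusted p = 0.0875 without WT air 4 weeks replicate 1.

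Vessel and contractile genes were lower in WT smoke at 4 weeks. Of 17 capillary endothelial genes, 6 fell over all genes tested and 8 adjusted over the list alone (adjusted p = 4.92e-05, and adjusted p = 0.0556 with an estimated correlation). They included the adrenomedullin receptor partner Ramp2 (-0.45 ± 0.07, adjusted p = 1.31e-05), Tmem100, a BMP-induced membrane protein gene (-0.43 ± 0.08, adjusted p = 6.29e-05), and the tight junction gene Cldn5 (-0.49 ± 0.10, adjusted p = 0.000662). Smooth muscle and pericyte genes were lower (6 of 15 fell, 6 adjusted over the list alone, adjusted p = 0.00891, adjusted p = 0.316 with an estimated correlation). They included Acta2 (-0.82 ± 0.16, adjusted p = 0.00029) and Cnn1 (-1.06, adjusted p = 0.000566), which encode contractile fibre proteins. BMP-SMAD targets were lower (1 of 14 rose and 5 fell, 1 and 7 adjusted over the list alone, adjusted p = 0.000443, adjusted p = 0.143 with an estimated correlation). They included Atoh8 (-0.55 ± 0.11, adjusted p = 0.00037). Targets of the aryl hydrocarbon receptor (AhR), which senses smoke components, went both ways. Cyp1a1 (1.57, adjusted p = 0.0237) and Cyp1b1 (0.56, adjusted p = 0.00447) were higher and the aldehyde dehydrogenase gene Aldh3a1 was lower (-1.04, adjusted p = 7.76e-07). Among the 8 AhR targets tested, 2 rose and 1 fell over all genes tested, and 2 and 2 adjusted over the list alone, with a median of 0.124 and a mean of 0.206 while the test leaned down (adjusted p = 0.939).

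**Figure D2:**
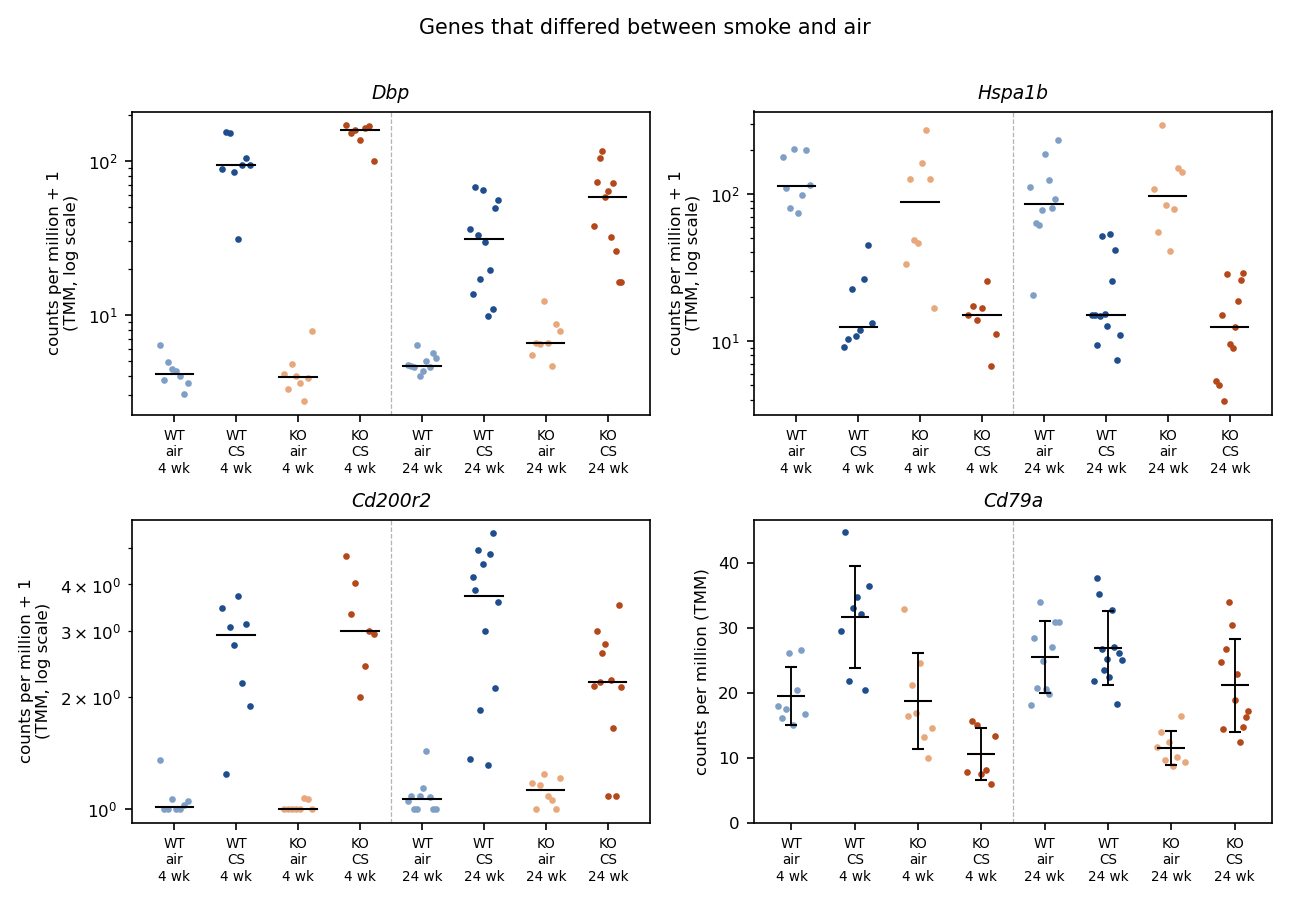
Levels of Dbp, Hspa1b and Cd200r2 (log scale of CPM + 1, with medians) and Cd79a (linear scale, mean ± SD) in the 8 groups, each point a library. Mean Dbp was 3.32 CPM in WT mice in air and 99.3 CPM in smoke at 4 weeks, and mean Cd79a in KO mice went from 18.7 to 10.5 CPM with smoke at 4 weeks and from 11.5 to 21.1 CPM at 24 weeks.

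After 24 weeks of smoke the WT lung had lower heat shock genes than in air, and 13 of 16 clock genes differed. In this comparison 1074 genes were higher and 1019 lower (2093 in all), 230 of them by more than 2-fold. Awat1, a wax ester synthesis gene, was at 0 in every WT library in air and at 2.57 ± 1.93 CPM in smoke (adjusted p = 1.61e-10). Cd200r2, a receptor gene of the CD200 receptor family (ENSMUSG00000090176, chromosome 16, 44687460 to 44736208), had the next highest fold change (4.72 ± 0.53, adjusted p = 4.53e-10). Ear6 (4.63, adjusted p = 4.59e-07), Ly6i (2.86, adjusted p = 3.72e-06) and Cxcr1 (2.92 ± 0.32, adjusted p = 2.02e-10) were high at this time as at 4 weeks. So were Stra6l (3.22 ± 0.36, adjusted p = 3.69e-10) and Dbp (3.08 ± 0.33, adjusted p = 9.69e-11). The others of the 10 highest were the defensin-like Spag11b (3.69, adjusted p = 2.55e-07), the anion exchanger pendrin (Slc26a4; 2.80 ± 0.36, adjusted p = 2.01e-08) and Arnt2, a partner of bHLH-PAS factors (2.68 ± 0.32, adjusted p = 2.03e-09).

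Lower in WT smoke at 24 weeks were the muscle fructose bisphosphatase Fbp2 (-3.27 ± 0.61, adjusted p = 7.11e-05), Snx31 (-2.75 ± 0.35, adjusted p = 1.23e-08), Hspa1b (-2.25 ± 0.39, adjusted p = 1.9e-05) and Hspa1a (-1.86, adjusted p = 0.000117). The adipocyte hormone gene Lep (-1.95, adjusted p = 0.00686) and the fatty acid binding protein gene Fabp1 (-1.70, adjusted p = 0.000123) fell with them. Matrix and surface genes in this set were Tnr (-1.82, adjusted p = 1.21e-06), Rptn (-1.52, adjusted p = 3.28e-05) and the aminopeptidase gene Lvrn (-1.44, adjusted p = 0.000914). The myeloid receptor gene Tarm1 (-1.70, adjusted p = 0.0255) lost its call when libraries were weighted by quality. Predicted models were 100 of the higher and 54 of the lower calls, and immunoglobulin or T cell receptor segments 2 and 9.

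Of 19 lipid-associated macrophage genes in WT smoke at 24 weeks, 14 rose and 0 fell over all genes tested, 14 and 1 adjusted over the list alone (adjusted p = 4.14e-06, and adjusted p = 0.0717 with an estimated correlation). Gpnmb went from 17.8 ± 5.16 to 85.3 ± 29.2 CPM (2.27 ± 0.22, adjusted p = 5.24e-12). Trem2 (2.06 ± 0.24, adjusted p = 2.46e-09), the integrin Itgax (1.24 ± 0.14, adjusted p = 9.55e-10) and the lysosomal protease Ctsd (0.95, adjusted p = 7.35e-09) also rose. Of 19 alveolar macrophage genes, 11 rose and 1 fell over all genes tested, 11 and 1 adjusted over the list alone (adjusted p = 7.88e-05, and adjusted p = 0.119 with an estimated correlation). Ctsk went from 28.3 ± 5.50 to 131 ± 50.5 CPM (2.21 ± 0.23, adjusted p = 9.93e-11). The vacuolar proton pump subunit Atp6v0d2 (1.63 ± 0.20, adjusted p = 4.34e-09) and the chitinase-like Chil3 (1.91 ± 0.24, adjusted p = 1.53e-08) rose with it. Of 20 proliferation genes, 11 rose over all genes tested and 17 adjusted over the list alone (adjusted p = 0.000195, and adjusted p = 0.119 with an estimated correlation). The mitotic genes Cenpe (0.93, adjusted p = 0.00017), Ccnb1 (0.99, adjusted p = 0.000287) and Top2a (0.59, adjusted p = 0.00301) were among them. Dendritic cell genes passed too (4 of 15 rose and 0 fell, 8 and 1 adjusted over the list alone, adjusted p = 0.0117, adjusted p = 0.499 with an estimated correlation). Ccl22 was at 1.22, adjusted p = 8.07e-06.

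Heat shock and unfolded protein genes were again lower (17 of 20 fell, 19 adjusted over the list alone, adjusted p = 1.92e-08, adjusted p = 0.00852 with an estimated correlation). Hspa8 was at -0.86 ± 0.10, adjusted p = 3.52e-09, and Hsp90aa1, a cytosolic chaperone, at -0.78 ± 0.13, adjusted p = 1.62e-05. Capillary genes were lower in WT smoke at 24 weeks (5 of 17 fell, 11 adjusted over the list alone, adjusted p = 0.000141, adjusted p = 0.119 with an estimated correlation). The guidance factor Sema3c was at -0.56 ± 0.09, adjusted p = 1.99e-06, and Ramp2 at -0.36 ± 0.06, adjusted p = 3.38e-05. Alveolar fibroblast genes were lower (3 of 15 fell, 3 adjusted over the list alone, adjusted p = 0.027, adjusted p = 0.541 with an estimated correlation). They included Fgf10, a growth factor for the epithelium (-0.45, adjusted p = 5.16e-05). Ciliated cell genes leaned higher (4 of 14 rose, 5 adjusted over the list alone, adjusted p = 0.0265, adjusted p = 0.541 with an estimated correlation). Iron handling genes did too (4 of 28 rose and 1 fell, 5 and 1 adjusted over the list alone, adjusted p = 0.0457, adjusted p = 0.554 with an estimated correlation). The list of cartilage and airway gland genes leaned lower, with 0 of 3 called (adjusted p = 0.0457, adjusted p = 0.554 with an estimated correlation). Alveolar transitional genes leaned higher (4 of 14 rose and 3 fell, 6 and 3 adjusted over the list alone, adjusted p = 0.0464, adjusted p = 0.554 with an estimated correlation). They had adjusted p = 0.0559 without WT CS 24 weeks replicate 1 and 0.05, no call, in another order of the groups in the model. Of 16 clock genes, 7 rose and 6 fell over all genes tested, and 7 and 7 adjusted over the list alone, with a median of -0.025 and a mean of 0.301 (adjusted p = 0.619). Of 14 neutrophil genes, 1 rose and 10 fell over all genes tested (adjusted p = 0.197 for the list), among them the chemokine receptor Cxcr2 (-1.17, adjusted p = 0.00897) and the calgranulin gene S100a9 (-1.40, adjusted p = 0.0159). The AhR repressor Ahrr (2.89 ± 0.36, adjusted p = 8.85e-09) and Cyp1b1 (0.93 ± 0.12, adjusted p = 1.7e-08) rose and Aldh3a1 fell (-0.59, adjusted p = 0.000658).

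In KO lungs at 4 weeks many of the genes called in WT lungs differed between smoke and air, with clock genes again among the highest and lowest. Higher genes numbered 876 and lower genes 755 (1631 in all), 240 of them by more than 2-fold. Cd200r2 (6.41 ± 0.75, adjusted p = 1.2e-09), Dbp (5.64 ± 0.40, adjusted p = 1.52e-18), Ear6 (3.92, adjusted p = 9.82e-05), Saa3 (3.56 ± 0.53, adjusted p = 8.57e-07) and Ly6i (3.28, adjusted p = 7.3e-06) were the 5 highest. Mmrn1, a platelet and endothelial multimerin gene, was at 0 in all 7 KO libraries in smoke, against a mean of 8.18 CPM in air (adjusted p = 0.0171). Other lower genes were Npas2 (-3.24 ± 0.28, adjusted p = 5.94e-15), Arntl (-3.12 ± 0.22, adjusted p = 1.4e-18) and Rptn (-2.89 ± 0.36, adjusted p = 5.2e-09). Predicted models were 63 of the higher and 44 of the lower calls, and immunoglobulin or T cell receptor segments 0 and 2.

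Of 16 clock genes in KO mice at 4 weeks, 9 rose and 4 fell over all genes tested, 9 and 4 adjusted over the list alone (adjusted p = 1.28e-13, and adjusted p = 0.00109 with an estimated correlation). The clock output gene Tef was at 1.89 ± 0.13, adjusted p = 1.4e-18. Lipid-associated macrophage genes rose (14 of 19 rose and 0 fell, 15 and 1 adjusted over the list alone, adjusted p = 3.01e-05, adjusted p = 0.0707 with an estimated correlation). Alveolar macrophage genes rose too (10 of 19 rose and 1 fell, 10 and 2 adjusted over the list alone, adjusted p = 0.000318, adjusted p = 0.134 with an estimated correlation). The macrophage elastase gene Mmp12 was at 2.62 ± 0.39, adjusted p = 8.99e-07. Dendritic cell genes were higher (7 of 15 rose and 1 fell, 7 and 2 adjusted over the list alone, adjusted p = 0.00478, adjusted p = 0.313 with an estimated correlation). So were iron handling genes (6 of 28 rose and 0 fell, 8 and 1 adjusted over the list alone, adjusted p = 0.000249, adjusted p = 0.134 with an estimated correlation). Ciliated cell genes were higher in part (3 of 14 rose, 3 adjusted over the list alone, adjusted p = 0.0384, adjusted p = 0.488 with an estimated correlation). Alveolar type 2 genes leaned higher (6 of 18 rose and 1 fell, 9 and 1 adjusted over the list alone, adjusted p = 0.0442, adjusted p = 0.488 with an estimated correlation), and the surfactant protein gene Sftpd was at 0.68 ± 0.13, adjusted p = 5.99e-05. B cell genes fell (7 of 15 fell, 10 adjusted over the list alone, adjusted p = 0.0236, adjusted p = 0.388 with an estimated correlation). Ms4a1, which encodes CD20, was at -0.84 ± 0.20, adjusted p = 0.00223, and Cd79a, a signalling chain of the B cell receptor, at -0.85 ± 0.21, adjusted p = 0.00328. Capillary genes were lower (8 of 17 fell, 9 adjusted over the list alone, adjusted p = 5.66e-05, adjusted p = 0.0707 with an estimated correlation). Heat shock and unfolded protein genes fell (0 of 20 rose and 13 fell, 1 and 13 adjusted over the list alone, adjusted p = 0.000811, adjusted p = 0.134 with an estimated correlation). Smooth muscle and pericyte genes leaned lower (2 of 15 fell, 2 adjusted over the list alone, adjusted p = 0.0236, adjusted p = 0.374 with an estimated correlation). The large-vessel and lymphatic list, which holds Mmrn1, was lower as well (2 of 13 fell, 4 adjusted over the list alone, adjusted p = 0.00179, adjusted p = 0.134 with an estimated correlation). Cyp1a1 rose (2.40 ± 0.52, adjusted p = 0.000788).

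In KO lungs at 24 weeks heat shock genes were lower in smoke than in air. Higher genes numbered 609 and lower genes 756 (1365 in all), 171 of them by more than 2-fold, and 742 were called without 3 KO libraries in air of high Cyp1a1. Awat1 went from 0.0315 ± 0.0452 to 1.75 ± 1.56 CPM (adjusted p = 8.86e-07). Dbp (3.11 ± 0.34, adjusted p = 1.91e-09), Ear6 (3.00, adjusted p = 0.0021), Arnt2 (2.68 ± 0.36, adjusted p = 2.18e-07) and the interleukin 9 receptor gene Il9r (2.29, adjusted p = 0.00565) followed. Hspa1b (-3.09 ± 0.43, adjusted p = 3.13e-07) and Hspa1a (-2.67 ± 0.40, adjusted p = 1.66e-06) were lower. Clca1, a goblet cell gene, had a log2 fold change of -7.10, adjusted p = 1.08e-07, but of -1.34, adjusted p = 0.305, without KO air 24 weeks replicate 2, which held it at 588 CPM. The interferon-induced chemokine gene Cxcl9 (-1.86, adjusted p = 0.0329) had -1.15, adjusted p = 0.258, without that library and lost its call without KO CS 24 weeks replicate 1 (-1.77). Mmrn1 had a mean of 4.48 CPM in air and 0.00689 CPM in smoke (adjusted p = 0.0252), with adjusted p = 0.0835 without the former library and 0.0555 without the latter. Predicted models were 90 of the higher and 24 of the lower calls, and immunoglobulin or T cell receptor segments 35 and 1.

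Of 20 heat shock and unfolded protein genes in KO mice at 24 weeks, 18 fell over all genes tested and 19 adjusted over the list alone (adjusted p = 1.88e-10, and adjusted p = 0.000526 with an estimated correlation). Hspa8 was at -0.96 ± 0.11, adjusted p = 5.19e-09, and Hspa5 at -0.72 ± 0.09, adjusted p = 1.52e-08. B cell genes rose (11 of 15 rose, 14 adjusted over the list alone, adjusted p = 0.00265, adjusted p = 0.27 with an estimated correlation). Fcer2a was at 1.64 ± 0.27, adjusted p = 1.4e-05, and Cd79a at 0.88 ± 0.19, adjusted p = 0.000908. Plasma cell genes rose (4 of 15 rose and 1 fell, 6 and 1 adjusted over the list alone, adjusted p = 0.0112, adjusted p = 0.405 with an estimated correlation). The light chain gene Iglc1 was at 1.87, adjusted p = 0.000213. Capillary genes fell (7 of 17 fell, 10 adjusted over the list alone, adjusted p = 5.75e-05, adjusted p = 0.0508 with an estimated correlation). The large-vessel and lymphatic list with Mmrn1 in it fell too (1 of 13 rose and 4 fell, 1 and 6 adjusted over the list alone, adjusted p = 0.0146, adjusted p = 0.421 with an estimated correlation). Extracellular matrix genes fell (8 of 24 fell, 13 adjusted over the list alone, adjusted p = 0.0323, adjusted p = 0.425 with an estimated correlation). The cross-linking enzyme gene Lox was at -0.67, adjusted p = 0.000109, and the elastin gene Eln at -0.84, adjusted p = 0.000936. NRF2 antioxidant genes were lower (6 of 21 fell, 10 adjusted over the list alone, adjusted p = 0.0112, adjusted p = 0.413 with an estimated correlation). They had adjusted p = 0.762 without 3 KO libraries in air of high Cyp1a1 (replicates 3, 4 and 7). Cholesterol synthesis genes leaned higher (3 of 18 rose, 6 adjusted over the list alone, adjusted p = 0.0344, adjusted p = 0.425 with an estimated correlation). Ciliated genes did so too (2 of 14 rose, 2 adjusted over the list alone, adjusted p = 0.0344, adjusted p = 0.425 with an estimated correlation). Clock genes leaned higher (7 of 16 rose and 4 fell, 9 and 5 adjusted over the list alone, adjusted p = 0.0493, adjusted p = 0.43 with an estimated correlation). BMP-SMAD targets leaned lower (0 of 14 rose and 2 fell, 1 and 3 adjusted over the list alone, adjusted p = 0.0485, adjusted p = 0.43 with an estimated correlation). Alveolar fibroblast genes leaned the same way (4 of 15 fell, 4 adjusted over the list alone, adjusted p = 0.0424, adjusted p = 0.43 with an estimated correlation). Glucocorticoid-responsive genes were lower as well (1 of 15 rose and 3 fell, 1 and 4 adjusted over the list alone, adjusted p = 0.0424, adjusted p = 0.43 with an estimated correlation). Without KO air 24 weeks replicate 2 the ciliated, fibroblast, matrix, BMP-SMAD and clock lists had adjusted p of 0.0755, 0.0839, 0.0755, 0.0677 and 0.1. Without KO CS 24 weeks replicate 1 the fibroblast, matrix and glucocorticoid lists had 0.0775, 0.0775 and 0.0665. Without the 3 libraries of high Cyp1a1 the cholesterol, ciliated, clock, BMP-SMAD and fibroblast lists had 0.0884, 0.142, 0.305, 0.0839 and 0.16, while Ahrr (2.01, adjusted p = 8.3e-05) led AhR targets that then passed (3 rose, adjusted p = 0.00167).

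Genes called in both genotypes mostly moved the same way with smoke. At 4 weeks 315 genes rose and 301 fell in both, where independent lists would share 37.6 and 35.5, and 8 genes went opposite ways. At 24 weeks 304 rose and 425 fell in both (38.1 and 44.9 for independent lists), and 2 went opposite ways. Across genes the fold changes of the genotypes had a Pearson correlation of 0.465 at 4 weeks and 0.428 at 24 weeks, and genes are not independent replicates. Between 4 and 24 weeks in WT mice 321 genes rose and 354 fell at both times (46.1 and 48 for independent lists), with a Pearson correlation of 0.418 across genes. In KO mice these numbers were 229 and 261 (31.1 and 33.3), with a correlation of 0.317.

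In air at 4 weeks KO lungs had lower BMP-SMAD targets and some lower iron genes, and few genes differed by much. The KO lung had less Wnt10b and Hamp and more Muc5b and Zbtb16 than the WT lung. In this comparison 240 genes were higher and 276 lower in KO mice (516 in all), 33 of them by more than 2-fold. Among genes open to naming, Zbtb16, a transcription factor induced by glucocorticoids, had the highest fold change (2.44 ± 0.46, adjusted p = 0.00121), from 18.1 ± 3.70 to 102 ± 113 CPM. Nr1d1 (1.98 ± 0.29, adjusted p = 9.1e-06) and Nr1d2 (1.09 ± 0.20, adjusted p = 0.000744) were higher, as was Muc5b, the main gel-forming mucin gene of the airway (1.59 ± 0.31, adjusted p = 0.00182). The others were the hypoxia factor gene Hif3a (1.62, adjusted p = 0.00478), the proteoglycan gene Vcan (1.31, adjusted p = 0.00272) and Ifitm6 (1.29, adjusted p = 0.00432). Last came the muscle genes Mettl21e (1.21, adjusted p = 0.0259) and Cavin4 (1.08, adjusted p = 0.0447), and Arhgef37 (1.18 ± 0.21, adjusted p = 0.000567). Lower besides Bmp6 were Wnt10b, a ligand of the WNT pathway (ENSMUSG00000022996, chromosome 15, 98668593 to 98690045; -1.14 ± 0.15, adjusted p = 1.8e-07), and Hamp, which encodes the iron hormone hepcidin (-2.18 ± 0.45, adjusted p = 0.00301). The histone gene H2bc4 (-0.99 ± 0.12, adjusted p = 1.3e-08), Ankrd1 (-1.20, adjusted p = 0.000631), Fhit (-1.17, adjusted p = 0.00297) and Trnp1 (-1.01, adjusted p = 0.00292) fell as well. The adhesion gene Ceacam2 (-4.35, adjusted p = 0.0493) and the protease gene Ctse (-2.29, adjusted p = 0.0208) lost their calls without WT air 4 weeks replicate 1 (-4.53 and -2.19), and so did Cavin4 (1.05). Ceacam2 (-4.30) and Cavin4 (1.08) also lost theirs without KO air 4 weeks replicate 8.

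Of 14 BMP-SMAD targets in air at 4 weeks, 1 rose and 8 fell over all genes tested, 1 and 10 adjusted over the list alone (adjusted p = 5.21e-05, and adjusted p = 0.0379 with an estimated correlation). They included Atoh8 (-0.63 ± 0.11, adjusted p = 0.000509), Id3 (-0.61 ± 0.12, adjusted p = 0.00203) and the BMP signal transducer gene Smad9 (-0.55 ± 0.13, adjusted p = 0.00776). Iron genes fell in part, with the transferrin receptor gene Tfrc (ENSMUSG00000022797, chromosome 16, 32427556 to 32451612) at -0.79 ± 0.12, adjusted p = 1.55e-05, and the ferritin heavy chain gene Fth1 at -0.60 ± 0.09, adjusted p = 1.72e-05. The iron handling list did not move on balance (0 of 28 rose and 3 fell, 4 and 4 adjusted over the list alone, adjusted p = 0.872) but changed in either direction (adjusted p = 0.00364). Heat shock genes were lower (3 of 20 fell, 10 adjusted over the list alone, adjusted p = 0.0145, adjusted p = 0.348 with an estimated correlation), as were alveolar transitional genes (2 of 14 fell, 4 adjusted over the list alone, adjusted p = 0.0418, adjusted p = 0.528 with an estimated correlation). The large-vessel and lymphatic list, which holds Mmrn1, was higher (2 of 13 rose, 2 adjusted over the list alone, adjusted p = 0.0204, adjusted p = 0.348 with an estimated correlation). These 3 lists had adjusted p of 0.0754, 0.214 and 0.0771 without WT air 4 weeks replicate 1. The count of calls was 144 without it, 300 without KO air 4 weeks replicate 8, and 34 when only the 2 groups were fitted, where Zbtb16, Hamp, Hif3a, Vcan, Ifitm6, Mettl21e, Cavin4, Arhgef37, Ankrd1, Fhit and Id3 lost their calls. Higher genes were 72% of 125 calls without 4 outlying libraries against 46.5% of the 516.

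In smoke at 4 weeks B cell genes were lower in KO lungs. Between KO and WT mice 92 genes were higher and 117 lower (209 in all), 75 of them by more than 2-fold. The count was 424 with only these groups fitted, 444 with RNA quality covariates and 833 with quality weights. Of 15 B cell genes, 14 fell over all genes tested and 15 adjusted over the list alone (adjusted p = 2.08e-06, and adjusted p = 0.00103 with an estimated correlation). Cd79a was at 31.6 ± 7.84 CPM in WT and 10.5 ± 4.03 CPM in KO mice (-1.58 ± 0.21, adjusted p = 4.13e-07). Ms4a1 (-1.40 ± 0.20, adjusted p = 2.28e-06), Cd79b (-1.07 ± 0.17, adjusted p = 5.55e-05) and the scaffold gene Bank1 (-1.51 ± 0.25, adjusted p = 0.000111) were lower as well. The complement receptor gene Cr2 of B cells (-1.86 ± 0.44, adjusted p = 0.0128) was among the 5 lowest open to naming. The others were Bmp6, Ceacam2 (-6.26, adjusted p = 0.0132), the albumin gene Alb (-2.39, adjusted p = 0.0157) and Eif3j2 (-2.46, adjusted p = 0.0117), which has a near-identical copy. The highest open to naming were Fbp2 (3.29, adjusted p = 0.0083), Zbtb16 (2.21 ± 0.45, adjusted p = 0.00232) and the neutrophil chemokine gene Cxcl1 (2.04, adjusted p = 0.0205). They were followed by Dcstamp, which acts in the fusion of macrophages (1.63, adjusted p = 0.0363), and the clotting cofactor gene Proz (1.62 ± 0.26, adjusted p = 6.65e-05). Club and secretory cell genes (2 of 15 rose, 7 adjusted over the list alone, adjusted p = 0.0284, adjusted p = 0.203 with an estimated correlation), among them Muc5b (1.35, adjusted p = 0.0142), were higher in KO mice. Glucocorticoid-responsive genes were higher (2 of 15 rose, 5 adjusted over the list alone, adjusted p = 0.0441, adjusted p = 0.238 with an estimated correlation). Fkbp5 was at 1.32 ± 0.23, adjusted p = 0.000253. Clock genes were higher on balance (1 of 16 rose and 2 fell, 7 and 3 adjusted over the list alone, adjusted p = 0.0284, adjusted p = 0.203 with an estimated correlation), while the clock activator Arntl was lower (-1.33 ± 0.22, adjusted p = 8.51e-05). Tfrc was lower in smoke as in air (-0.69 ± 0.12, adjusted p = 0.000271), and iron handling genes changed in either direction (1 of 28 rose and 2 fell, 5 and 4 adjusted over the list alone, adjusted p = 0.0216).

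At 24 weeks in air KO lungs had lower Tfrc and Wnt10b than WT lungs, and higher antioxidant genes. Higher genes numbered 784 and lower genes 604 (1388 in all), 191 of them by more than 2-fold, but 351 and 361 (712 in all) without 3 KO libraries of high Cyp1a1. Wnt10b went from 27.2 ± 4.73 (SD, n = 10) CPM in WT to 6.14 ± 2.18 (SD, n = 8) CPM in KO mice (-2.17 ± 0.15, adjusted p = 7.55e-19). Tfrc went from 102 ± 12.6 to 34.2 ± 7.67 CPM (-1.58 ± 0.12, adjusted p = 2.93e-17). The erythroid and blood list, which holds some platelet genes, was not called (3 of 14 fell, adjusted p = 0.444). Of the 10 lowest open to naming 5 belong to platelets, which had no own list. They are the receptor genes Gp6 (-1.88, adjusted p = 0.000882), Gp5 (-1.87, adjusted p = 0.000126) and Gp1ba (-1.82, adjusted p = 0.000263). The tubulin gene Tubb1 (-1.72 ± 0.22, adjusted p = 6.3e-08) and Ppbp (-1.65 ± 0.27, adjusted p = 1.45e-05) follow. Il9r (-2.38, adjusted p = 0.00506) and the guidance factor gene Draxin (-2.38 ± 0.42, adjusted p = 7.33e-05) were the others beside Bmp6. Highest was Clca1 (6.54, adjusted p = 8.99e-07), but it had 0.72, adjusted p = 0.596, without KO air 24 weeks replicate 2, and the mucin gene Muc5ac (2.27, adjusted p = 0.00105) had 0.63, adjusted p = 0.347. Retnla, a gene of type 2 inflammation (2.11 ± 0.28, adjusted p = 2.48e-07), the mucous cell gene Agr2 (2.20, adjusted p = 0.000654) and Gp2 (2.01, adjusted p = 0.00137) were higher. So were Atp10b (1.99, adjusted p = 0.000147), Cxcl9 (2.97, adjusted p = 0.00128) and Zbtb16 (1.99, adjusted p = 0.001). Without replicate 2 Cxcl9 was at 2.26, adjusted p = 0.0142, and Retnla at 1.25, adjusted p = 3.14e-05. Cxcl9 held 24.6 and 22.0 CPM in replicates 2 and 8 and 0.416 to 1.66 CPM in the other KO libraries. Cyp1a1 (1.87, adjusted p = 0.003) turned to -1.10, adjusted p = 0.0916, and the cystine transporter gene Slc7a11 (1.73, adjusted p = 0.000217) to 0.88, adjusted p = 0.132, without those 3 libraries. They held Cyp1a1 at 233, 113 and 104 CPM, against 6.24 to 9.38 CPM in the other 5.

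Of 21 NRF2 antioxidant genes in air at 24 weeks, 14 rose over all genes tested and 18 adjusted over the list alone (adjusted p = 7.44e-09, and adjusted p = 0.00455 with an estimated correlation). Of them 8 rose without the 3 libraries of high Cyp1a1 (adjusted p = 0.000213). They included the sulfiredoxin gene Srxn1 (0.70 ± 0.09, adjusted p = 1.37e-08), the glutathione synthesis gene Gclm (0.52 ± 0.06, adjusted p = 1.47e-08) and the haem oxygenase gene Hmox1 (0.77 ± 0.11, adjusted p = 4.19e-07). AhR targets (4 of 8 rose, 5 adjusted over the list alone, adjusted p = 0.00185, adjusted p = 0.198 with an estimated correlation) had adjusted p = 0.218 without those 3 libraries. Club and secretory genes rose (6 of 15 rose, 12 adjusted over the list alone, adjusted p = 8.81e-05, adjusted p = 0.0675 with an estimated correlation). Muc5b was at 1.51 ± 0.29, adjusted p = 0.000286, and Ltf, the lactoferrin gene, at 1.24, adjusted p = 0.0037. Ciliated cell genes were higher (4 of 14 rose, 10 adjusted over the list alone, adjusted p = 0.00191, adjusted p = 0.198 with an estimated correlation). Alveolar transitional genes were too (3 of 14 rose, 3 adjusted over the list alone, adjusted p = 0.0027, adjusted p = 0.209 with an estimated correlation), with the keratin genes Krt18 (0.41 ± 0.07, adjusted p = 2.15e-05) and Krt8 (0.33 ± 0.07, adjusted p = 0.0013) among them. Proliferation genes leaned higher (4 of 20 rose, 10 adjusted over the list alone, adjusted p = 0.0415, adjusted p = 0.466 with an estimated correlation), as did dendritic cell genes (2 of 15 rose and 1 fell, 5 and 1 adjusted over the list alone, adjusted p = 0.0422, adjusted p = 0.473 with an estimated correlation). These lists had adjusted p of 0.101 and 0.0821 without KO air 24 weeks replicate 2, and the dendritic list 0.132 without the 3 libraries of high Cyp1a1. Iron handling genes went both ways (6 of 28 rose and 5 fell, 8 and 5 adjusted over the list alone, adjusted p = 0.497 on balance and adjusted p = 1.26e-25 in either direction). The ferritin light chain gene Ftl1 was higher (0.70 ± 0.09, adjusted p = 9.51e-08) and Fth1 lower (-0.62 ± 0.09, adjusted p = 1.05e-06).

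Lower lists in air at 24 weeks were led by B cell genes (14 of 15 fell, 15 adjusted over the list alone, adjusted p = 0.000139, adjusted p = 0.0675 with an estimated correlation). Cd79a was at -1.15 ± 0.19, adjusted p = 2.88e-05, and Cd79b at -0.97 ± 0.16, adjusted p = 2.82e-05. Plasma cell genes fell (5 of 15 fell, 6 adjusted over the list alone, adjusted p = 0.000871, adjusted p = 0.0889 with an estimated correlation). The heavy chain gene Ighm was at -1.34 ± 0.20, adjusted p = 1.76e-06. Aerocytes, the gas exchange capillary cells, had lower genes in KO mice (5 of 11 fell, 7 adjusted over the list alone, adjusted p = 8.81e-05, adjusted p = 0.0564 with an estimated correlation). Their peptide Apln was at -0.35, adjusted p = 0.00483. Other capillary genes were lower (1 of 17 rose and 2 fell, 1 and 5 adjusted over the list alone, adjusted p = 0.0141, adjusted p = 0.209 with an estimated correlation). Smooth muscle and pericyte genes fell (4 of 15 fell, 7 adjusted over the list alone, adjusted p = 0.0141, adjusted p = 0.209 with an estimated correlation), among them the receptor gene Pdgfrb (-0.57, adjusted p = 0.00228). BMP-SMAD targets fell (4 of 14 fell, 4 adjusted over the list alone, adjusted p = 0.000871, adjusted p = 0.0889 with an estimated correlation). Smad9 was at -0.80 ± 0.12, adjusted p = 3.27e-06, Id4 at -0.60 ± 0.12, adjusted p = 0.000775, and Hamp at -2.01, adjusted p = 0.00456. Mitochondrial transcripts took 2.38 ± 0.63% of counts in KO libraries and 1.90 ± 0.14% in WT libraries in air at 24 weeks.

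At 24 weeks in smoke KO lungs had lower Hamp, Tfrc and Wnt10b than WT lungs. Higher genes numbered 1248 and lower genes 1111 (2359 in all), 103 of them by more than 2-fold. Hamp went from 2.78 ± 1.26 to 0.245 ± 0.257 CPM (ENSMUSG00000050440, chromosome 7, 30641766 to 30643990; -3.46 ± 0.44, adjusted p = 5.43e-08), and Tfrc fell (-1.48 ± 0.10, adjusted p = 6.87e-19), as did Wnt10b (-1.72 ± 0.13, adjusted p = 1.34e-17). Mmrn1 had means of 12.2 and 0.00689 CPM in WT and KO mice (adjusted p = 0.00184). The atrial hormone gene Nppa was lower too (-2.37 ± 0.51, adjusted p = 0.00106). Highest of the genes open to naming were Fbp2 (2.54, adjusted p = 0.00326), the airway secretory gene Bpifa1 (1.94, adjusted p = 0.029), Hif3a (1.32, adjusted p = 0.00183), Zbtb16 (1.23, adjusted p = 0.0201) and the RNA-binding protein gene Igf2bp1 (1.23 ± 0.22, adjusted p = 9.62e-05).

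Of 24 extracellular matrix genes in smoke at 24 weeks, 19 fell over all genes tested and 21 adjusted over the list alone (adjusted p = 3.79e-05, and adjusted p = 0.0572 with an estimated correlation). With the mitochondrial share and mean exon length in the model 7 fell (adjusted p = 0.00161). Col1a1, a fibrillar collagen gene, went from 199 ± 36.0 to 128 ± 27.6 CPM (-0.64 ± 0.12, adjusted p = 0.000163), and Loxl1 (-0.58 ± 0.10, adjusted p = 5.49e-05) and the tenascin gene Tnc (-1.01 ± 0.22, adjusted p = 0.00131) fell. Smooth muscle and pericyte genes were lower (10 of 15 fell, 12 adjusted over the list alone, adjusted p = 2.66e-05, adjusted p = 0.0572 with an estimated correlation). They included Des (-0.44 ± 0.09, adjusted p = 0.000832) and Pdgfrb (-0.52 ± 0.11, adjusted p = 0.00133). Aerocyte genes were lower (6 of 11 fell, 6 adjusted over the list alone, adjusted p = 1.9e-05, adjusted p = 0.0572 with an estimated correlation), with Apln at -0.50 ± 0.08, adjusted p = 5.08e-06. Other capillary genes fell with them (1 of 17 rose and 7 fell, 1 and 9 adjusted over the list alone, adjusted p = 0.000389, adjusted p = 0.0997 with an estimated correlation). The fenestral diaphragm gene Plvap was at -0.45 ± 0.07, adjusted p = 2.6e-05, and the VEGF receptor gene Kdr at -0.36, adjusted p = 0.00252. The large-vessel and lymphatic list, which holds Mmrn1, fell too (1 of 13 rose and 5 fell, 1 and 6 adjusted over the list alone, adjusted p = 0.000814, adjusted p = 0.0997 with an estimated correlation). BMP-SMAD targets were lower (6 of 14 fell, 6 adjusted over the list alone, adjusted p = 9.83e-05, adjusted p = 0.0692 with an estimated correlation). They included Atoh8 (-0.65 ± 0.10, adjusted p = 3.94e-06) and Smad9 (-0.64 ± 0.11, adjusted p = 3.13e-05). BMP ligands, receptors and antagonists were lower (2 of 28 rose and 6 fell, 2 and 7 adjusted over the list alone, adjusted p = 0.0145, adjusted p = 0.269 with an estimated correlation).

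Several epithelial and detoxification genes were higher in KO mice in smoke at 24 weeks. Club and secretory genes were higher (10 of 15 rose, 13 adjusted over the list alone, adjusted p = 1.9e-05, adjusted p = 0.0572 with an estimated correlation). They included the carbonyl reductase gene Cbr2 (0.46 ± 0.07, adjusted p = 9.78e-06) and the secretoglobin gene Scgb3a2 (0.62, adjusted p = 0.00406; 0.39, adjusted p = 0.0416, without KO CS 24 weeks replicate 1). Ciliated cell genes were higher (9 of 14 rose, 10 adjusted over the list alone, adjusted p = 0.000421, adjusted p = 0.108 with an estimated correlation). NRF2 antioxidant genes rose (9 of 21 rose, 12 adjusted over the list alone, adjusted p = 0.000101, adjusted p = 0.0997 with an estimated correlation), and the glutathione transferase gene Gsta3 was at 0.47 ± 0.08, adjusted p = 1.39e-05. AhR targets rose as well (4 of 8 rose, 5 adjusted over the list alone, adjusted p = 0.000307, adjusted p = 0.0997 with an estimated correlation). Clock genes (6 of 16 rose and 2 fell, 7 and 2 adjusted over the list alone, adjusted p = 0.033, adjusted p = 0.456 with an estimated correlation) leaned higher. Iron genes went both ways (6 of 28 rose and 5 fell, 9 and 5 adjusted over the list alone, adjusted p = 1.17e-26 in either direction), with Fth1 at -0.69 ± 0.08, adjusted p = 1.21e-09. Markers of neighbouring tissue differed in the same comparison. Cardiac muscle genes were lower in KO libraries (6 of 14 fell, 10 adjusted over the list alone, adjusted p = 0.0113, adjusted p = 0.269 with an estimated correlation), and so were thymus genes (2 of 6 fell, 2 adjusted over the list alone, adjusted p = 0.000421, adjusted p = 0.0997 with an estimated correlation). Sex-linked genes (1 of 5 rose, 1 adjusted over the list alone, adjusted p = 0.0341, adjusted p = 0.456 with an estimated correlation) had adjusted p = 0.148 without KO CS 24 weeks replicate 1 and 0.0524 without WT CS 24 weeks replicate 1. Mitochondrial transcripts took 2.47 ± 0.77% of counts in KO and 2.00 ± 0.23% in WT libraries in smoke.

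**Figure D3:**
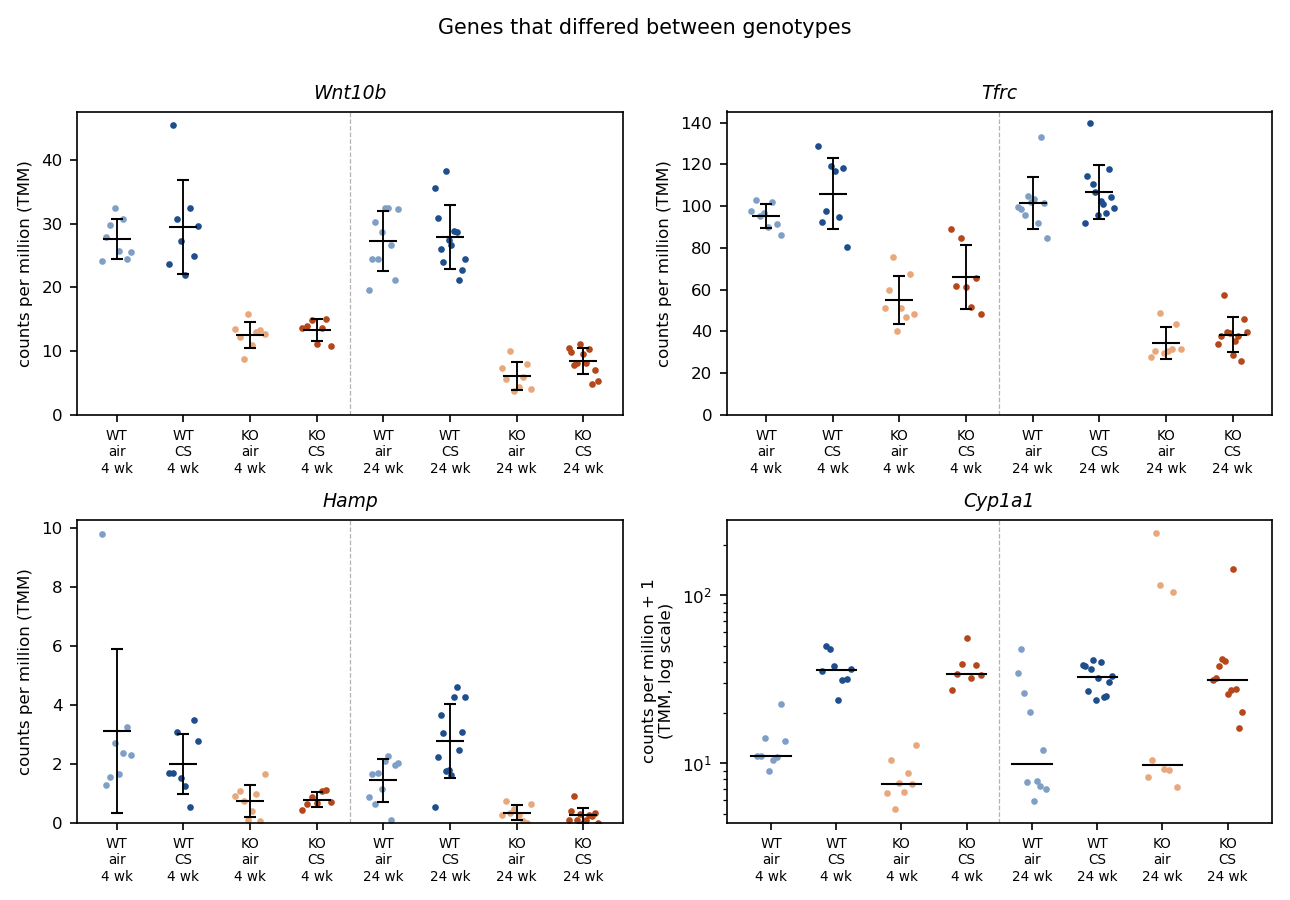
Levels of Wnt10b, Tfrc and Hamp (linear CPM, mean ± SD) and Cyp1a1 (log scale of CPM + 1, with medians) in the 8 groups, each point a library. Mean Tfrc was 102 and 107 CPM in WT mice and 34.2 and 38.2 CPM in KO mice at 24 weeks, in air and smoke.

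A set of 18 genes differed the same way between KO and WT mice at both times and in both exposures. The 9 lower genes included Bmp6, Wnt10b, Tfrc, Atoh8, Smad9, the GTPase gene Rnd1, the adhesion gene Flrt3 and the synaptic gene Insyn2a. The 9 higher genes were Zbtb16, Muc5b, Qsox1, Txndc5, Cage1, Cecr2, Fam13a, Mcf2l and the pseudogene Gm6505. Genes within 10 Mb of Bmp6 were called more often than others, 11 of 103 (10.68%) against 504 of 17059 (2.95%) in air at 4 weeks (odds ratio 3.93, Fisher's exact p = 0.000264, two-sided). In air at 24 weeks these were 23 of 103 (22.33%) against 1364 of 17059 (8%; odds ratio 3.31, Fisher's exact p = 6.09e-06). Of the 18 genes, 2 besides Bmp6 lay in that window, Cage1 and Txndc5 (odds ratio 22.5, Fisher's exact p = 0.00457).

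The genotype difference at 24 weeks was shared by the exposures. In air and in smoke 396 genes were higher and 310 lower in KO mice (57 and 39.1 for independent lists), 1 went opposite ways, and the Pearson correlation of fold changes across genes was 0.374. At 4 weeks the 2 exposures shared 19 higher and 17 lower genes (1.3 and 1.9 for independent lists), with a correlation of 0.17. Between 4 and 24 weeks in air 27 higher and 27 lower genes were shared (11 and 9.7), with a correlation of 0.034. Genes are not independent replicates.

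The smoke response itself differed between genotypes at 4 weeks, where 17 genes had a higher and 54 a lower response in KO than in WT mice (71 in all). Of 15 B cell genes, 10 fell over all genes tested and 15 adjusted over the list alone (adjusted p = 0.000451, and adjusted p = 0.0147 with an estimated correlation). Pou2af1, a B cell transcriptional coactivator (-2.04 ± 0.38, adjusted p = 0.00299), Fcmr (-1.87 ± 0.38, adjusted p = 0.00478) and Bank1 (-1.83 ± 0.35, adjusted p = 0.00299) were among the 5 lowest differences. The calcium channel gene Cacna1i (-2.16, adjusted p = 0.0461) and the urea transporter gene Slc14a1 (-1.78, adjusted p = 0.0461) were the others. Among the highest differences were Ptprn (1.14, adjusted p = 0.0206), the clock genes Per2 (1.02, adjusted p = 0.0386) and Cry1 (0.78 ± 0.16, adjusted p = 0.00492), and Cys1 (0.79, adjusted p = 0.036). Cacna1i (-2.02), Slc14a1 (-1.66), Ptprn (1.00) and Cys1 (0.75) lost their calls without WT air 4 weeks replicate 1, and Slc14a1 (-1.77), Cys1 (0.74) and Per2 (1.00) without KO air 4 weeks replicate 8. The count was 39 without the former library. At 24 weeks 3 genes had a different response (6 without WT CS 24 weeks replicate 1, 13 without the 3 libraries of high Cyp1a1), named here after their values were seen. All 3 lost their calls (adjusted p = 0.149) with only these groups fitted, and the light chain genes also with quality weights. Ahnak2 had a lower one (-0.81, adjusted p = 0.0432, and -0.74, adjusted p = 0.0692, without the 3 libraries of high Cyp1a1). Higher ones were those of the light chain genes Igkv3-2 (4.10, adjusted p = 0.0115) and Iglc1 (2.47, adjusted p = 0.0126). Plasma cell genes had a higher response in KO mice at 24 weeks (1 of 15 rose, 4 adjusted over the list alone, adjusted p = 0.0345, adjusted p = 0.036 with an estimated correlation).

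In WT mice 19 genes had a higher and 15 a lower response to smoke at 24 than at 4 weeks (34 in all), and 3 of 60 splits of the libraries, the real one included, gave as many. Clock genes had a lower one (1 of 16 rose and 7 fell, 3 and 10 adjusted over the list alone, adjusted p = 0.000776, adjusted p = 0.0221 with an estimated correlation). Nr1d1 was at -2.27 ± 0.37, adjusted p = 0.000302, Nr1d2 at -1.70 ± 0.26, adjusted p = 8.26e-05, and Hlf at -1.36 ± 0.24, adjusted p = 0.00146. Per1 (-1.18, adjusted p = 0.0487) lost its call without WT air 4 weeks replicate 1 (-1.06) or WT CS 24 weeks replicate 1 (-1.15), and the meiotic gene Tex11 (-1.63, adjusted p = 0.0339) without the former (-1.49). Contractile genes Cnn1 (1.49 ± 0.29, adjusted p = 0.00563) and Actg2 (1.33 ± 0.27, adjusted p = 0.00913) had the highest differences, with Fam124b (1.25, adjusted p = 0.0141), Galnt16 (1.22, adjusted p = 0.0275) and Spon2 (1.19, adjusted p = 0.0305). In KO mice 89 genes had a higher and 79 a lower response at 24 weeks (168 in all). B cell genes had a higher one (13 of 15 rose, 15 adjusted over the list alone, adjusted p = 0.00016, adjusted p = 0.00539 with an estimated correlation). Pou2af1 was at 2.31 ± 0.38, adjusted p = 0.000121, and Cr2 at 2.38, adjusted p = 0.0249. Plasma cell genes did too (2 of 15 rose, 5 adjusted over the list alone, adjusted p = 0.0385, adjusted p = 0.152 with an estimated correlation).

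Clock genes of KO mice had a lower response at 24 than at 4 weeks (2 of 16 rose and 9 fell, 3 and 11 adjusted over the list alone, adjusted p = 2.63e-05, adjusted p = 0.00368 with an estimated correlation). Dbp was at -2.53 ± 0.51, adjusted p = 0.00224, while the clock activator Npas2 had a higher one (2.11 ± 0.35, adjusted p = 0.000131). The highest differences also held Cacna1i (2.62, adjusted p = 0.00528) and Il9r (2.91, adjusted p = 0.0493). The lowest held Tex11 (-1.89, adjusted p = 0.00394), Dcstamp (-2.45, adjusted p = 0.0363; -2.35 and no call without KO CS 24 weeks replicate 1), Cyp1a1 (-3.05, adjusted p = 0.00646) and Slc7a11 (-1.92, adjusted p = 0.0219). Without the 3 libraries of high Cyp1a1 the last pair had -0.08 and -1.07 and neither passed, and Il9r (2.99) lost its call. Iron handling genes had a lower response at 24 weeks (1 of 28 fell, 2 adjusted over the list alone, adjusted p = 0.0218, adjusted p = 0.152 with an estimated correlation). This list had adjusted p = 0.0612 without those 3 libraries. NRF2 genes did as well (2 of 21 fell, 5 adjusted over the list alone, adjusted p = 0.0385, adjusted p = 0.201 with an estimated correlation). They had adjusted p = 0.5 without those libraries, 0.0607 without KO air 4 weeks replicate 8 and 0.0589 without KO CS 24 weeks replicate 1. Each time had its own air controls, which may also differ in age, cohort and hour of collection.

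**Figure D4:**
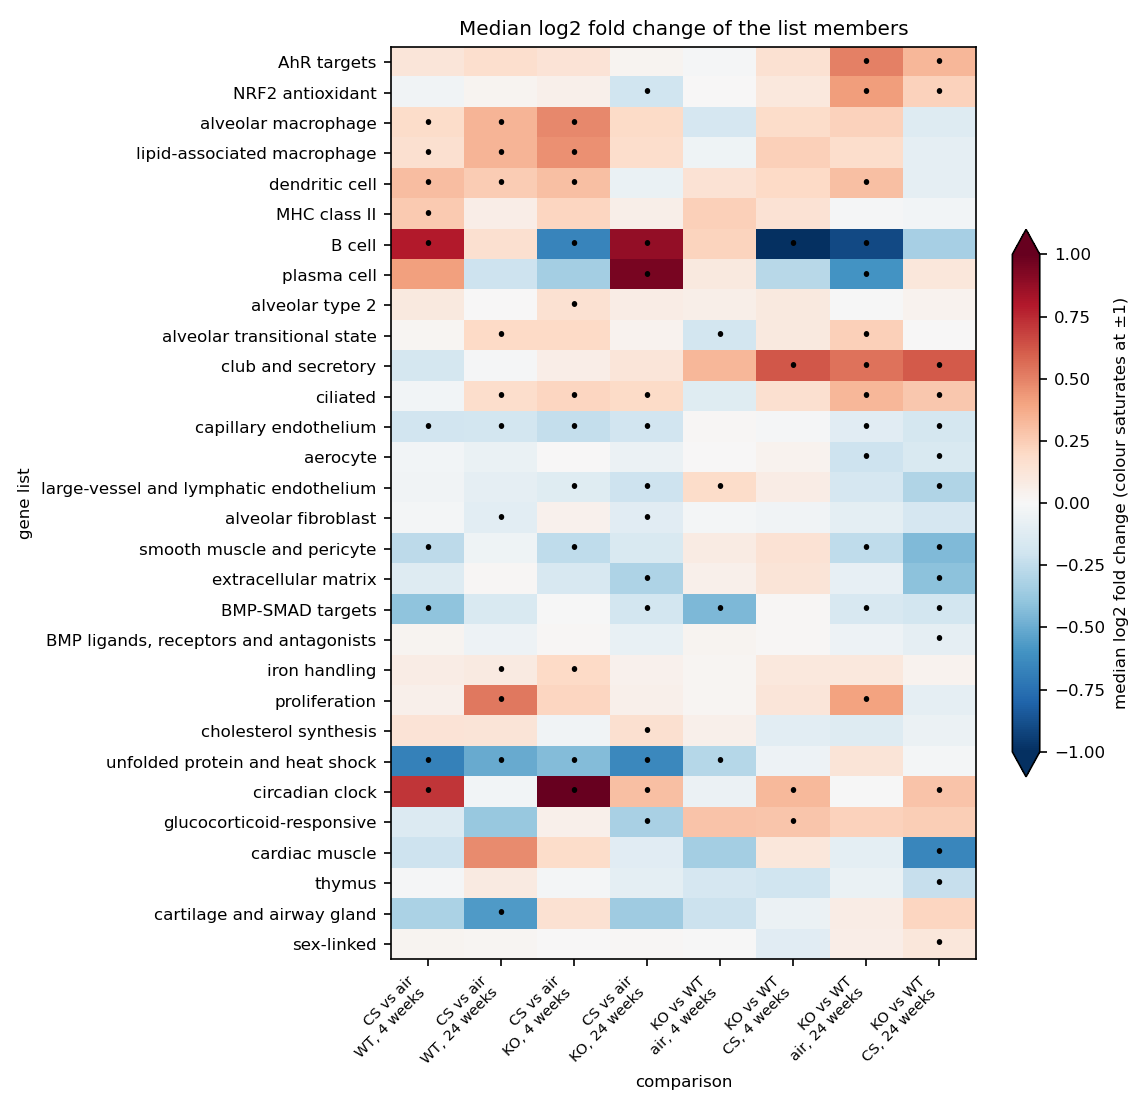
Median log2 fold change of 30 gene lists (rows) in 8 comparisons (columns), with colour saturating at 1 above or below 0 and a dot where the list's adjusted p is under 0.05. Of the cells, 82 carry a dot, and heat shock genes are lower with smoke in all 4 smoke comparisons.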

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

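Chosen after the results were seen were the tests of a common clock shift, both tests of Mmrn1, and the test of a genotype effect at both times, while the other tests were chosen before.

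Of 78 tests for a library far from its group, 14 found one (about 1 in 20 by chance for normal values). Smoke groups of 24 weeks were not tested. Total counts were 42.4 M in WT air 4 weeks replicate 7, against 11.49 to 20.09 M in the others of that group, and its Cyp1a1 was 21.49 CPM against 7.955 to 13.09. WT air 4 weeks replicate 1 had a mean exon length of 6690 bases (others 7810 to 8061) and Hamp at 9.787 CPM (others 1.268 to 3.259). WT CS 4 weeks replicate 2 had 0.422% haemoglobin counts (others 0.0971 to 0.2305%) and Wnt10b at 45.53 CPM (others 22.01 to 32.46). Bmp6 was 21.3 CPM in KO air 4 weeks replicate 3 (others 35.81 to 47.96) and Dbp 6.87 CPM in KO air 4 weeks replicate 8 (others 1.757 to 3.809). Cyp1a1 was 54.8 CPM in KO CS 4 weeks replicate 4 (others 26.39 to 37.69) and 233 CPM in KO air 24 weeks replicate 3 (others 6.24 to 113). Zbtb16 was 91.95 CPM in WT CS 4 weeks replicate 8 (others 21.71 to 54.01). Clca1 was 2.259 CPM in WT air 4 weeks replicate 3 (others 0.0788 to 0.4656) and 588 CPM in KO air 24 weeks replicate 2 (others 0.1067 to 3.329). Tfrc was 133 CPM in WT air 24 weeks replicate 8 (others 84.85 to 104.8). The causes were not tested.

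Effects that differed between groups by a test of the difference itself covered 71 genes (genotype by smoke, 4 weeks), 3 genes (genotype by smoke, 24 weeks), 34 genes (time by smoke, WT) and 168 genes (time by smoke, KO). Each contrast was set beside other splits of the same libraries, 60 splits in all with the real one. Chance could be excluded for smoke in WT mice at 4 weeks (1545 genes, highest other split 230) and 24 weeks (2093, highest other 38), and in KO mice at 4 weeks (1631, highest other 394). It could be excluded for genotype in air at 4 weeks (516, highest other 53), smoke at 4 weeks (209, highest other 5), air at 24 weeks (1388, highest other 416) and smoke at 24 weeks (2359, highest other 355), and for genotype by smoke at 4 weeks (71, highest other 22). In others 2 of 60 splits, the real one included, called as many, so chance stays open. These were smoke in KO mice at 24 weeks (1365, highest other 1585) and genotype by smoke at 24 weeks (3, highest other 330). Others were time by smoke in KO mice (168, highest other 573) and, with 3 of 60, in WT mice (34, highest other 189). Why other splits called more was not tested.

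Clock genes shifted with smoke at both times and in both genotypes, while heat shock genes fell. At 4 and 24 weeks 15 and 12 of 16 clock genes in WT and 16 and 14 in KO mice moved as 1 shift would. As the hour of collection is not given, time of day cannot be told apart from smoke for these or heat shock genes. Cirbp and Rbm3, which rise in the cold, were higher in all 4 comparisons (lowest log2 fold change 0.345). A lower body temperature, from hour or smoke, stays open. Within the smoke groups the clock score rose with Cyp1a1 over 38 libraries (Pearson r = 0.45, permutation p = 0.0142, Spearman rho = 0.423, permutation p = 0.0143, r = 0.423 without the 2 farthest libraries, 1 relation tested). With the hour unknown, this cannot tell recent smoke from time of day. By group r was 0.837 in WT CS at 4 weeks (exact permutation p = 0.00925, adjusted over 4 groups 0.037, adjusted Spearman p = 0.0916, and r = 0.461 without the 2 farthest), 0.383 and 0.555 in KO CS at 4 and 24 weeks, and of the opposite sign in WT CS at 24 weeks (-0.184), where none of the last 3 passed.

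Mmrn1 was on or off in single libraries, above 0.5 CPM in 17 (14.14 to 38.41 CPM) and at 0.08 CPM or less in 55. Low depth is excluded, since the smallest Mmrn1 count expected in a library without it was 215.1. Genotype or smoke as the whole cause is excluded too, since 5 of the 8 groups held libraries of both kinds. Differences between the mice of a group stay open and were not tested, and calls of this gene between groups may reflect which mice were in them.

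The KO to WT difference at 24 weeks was alike in air and smoke (Pearson r = 0.374 across genes, which are not independent replicates). With mitochondrial share (higher in KO mice) and exon length as covariates r was 0.385, which cannot exclude RNA quality. Without the 4 outlying libraries r was 0.359, but those of high Cyp1a1 were not tested. A genotype effect present at both times cannot be told apart from one that grows with time, since the 4 correlations between the times ran from 0.034 to 0.355. Differences of litter or cohort between the genotypes at 24 weeks stay open and were not tested.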

How the results depend on the processing

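Chosen after the data were seen were the settings without 4 outlying libraries, without each of 5 libraries singly, without 3 KO air 24 weeks libraries of high Cyp1a1, with RNA quality covariates (mitochondrial share and mean exon length), and, for the lists, with the groups in another order.

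Of 385 results for genes named in the report, 300 kept direction and call in every alternative run for them. Over their 4093 alternatives 3878 kept the call, 214 lost it with the same direction, and 1 reversed: Cyp1a1 in KO against WT mice in air at 24 weeks was -1.10 (adjusted p = 0.0916) without the 3 libraries of high Cyp1a1, which held most of it. Of 132 alternatives for the 12 counts of calls, 91 stayed within 1.5 times the reported count and 41 did not. The overlaps of smoke responses (8 of 8) and the calls near Bmp6 (6 of 6, windows of 5 and 20 Mb) kept their side. Of 90 lists called by fry, 11 kept their call in every alternative and 12 were called by camera with an estimated correlation. With only the groups compared 29 lost their call, with RNA quality covariates 10, and without the 4 outlying libraries 9. The p values of fry moved a little with the order in which the groups enter the model, and 89 lists were called in another order.

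The cause was not tested for the counts that moved. Quality weights in voom gave 2441 calls for smoke in WT mice at 4 weeks, 3184 at 24 weeks, 2566 in KO mice at 4 weeks, 302 for genotype in air and 833 in smoke at 4 weeks, 129 for genotype by smoke at 4 weeks, and 69 and 270 for time by smoke in WT and KO mice. Under these weights 37 results for genes lost their calls, and with only the groups compared 44. Without a filter on low counts, genotype in air at 4 weeks had 248 calls and genotype by smoke 43 at 4 weeks and 6 at 24 weeks, where a filter at a mean CPM of 1 gave 5. With only the groups compared, genotype at 4 weeks had 34 calls in air and 424 in smoke. Genotype by smoke at 24 weeks then had 0 calls, where 1030 genes had an unadjusted p under 0.05. With all groups fitted, DESeq2 called 19 and voom 2. DESeq2 gave 123 for genotype by smoke at 4 weeks and 58 and 257 for time by smoke in WT and KO mice. With 2 surrogate variables the counts were 209 and 356 for genotype in air and smoke at 4 weeks, 2092 in air at 24 weeks, 5 for genotype by smoke at 24 weeks, and 286 for time by smoke in KO mice.

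Without the 4 outlying libraries genotype had 125 calls in air and 381 in smoke at 4 weeks and 2205 in air at 24 weeks, genotype by smoke 10 at 24 weeks, and time by smoke 256 in KO mice. With RNA quality covariates the counts were 2110 for smoke in KO mice at 24 weeks, 165 and 444 for genotype in air and smoke at 4 weeks, 20 for genotype by smoke at 24 weeks, and 360 for time by smoke in KO mice. Without the 3 libraries of high Cyp1a1 smoke in KO mice had 742 calls, genotype in air 712 and genotype by smoke 13 at 24 weeks. Leaving out single libraries gave 144 (without WT air 4 weeks replicate 1) to 300 (without KO air 4 weeks replicate 8) for genotype in air at 4 weeks. It gave 39 (without the former) to 59 for genotype by smoke at 4 weeks, and 3 to 6 (without WT CS 24 weeks replicate 1) at 24 weeks.

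No paired analysis was possible because the labels give no replicate number within a group, and sex was not run as a covariate because every library looked male (Xist at most 0.74 CPM). Depth limits genes of low level, as the shallowest library held 3.74 M counts.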

Other observations

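No test in this part was chosen after its result was seen, but the libraries and genes given as levels were.

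In air at 4 weeks 3 of 17 alveolar type 1 genes were lower in KO mice and 0 higher (6 and 0 adjusted over the list alone, adjusted p = 0.201 for the list), namely the receptor gene Ager (-0.28 ± 0.08, adjusted p = 0.0314), the water channel gene Aqp5 (-0.22 ± 0.06, adjusted p = 0.0244) and Hopx (-0.32 ± 0.09, adjusted p = 0.0334). In smoke at 24 weeks 1 rose and 5 fell (adjusted p = 0.332 for the list), with the matrix genes Spock2 at -0.60 ± 0.10, adjusted p = 1.82e-05, and Col4a3 at -0.48 ± 0.11, adjusted p = 0.00244. Among platelet genes Ppbp (-0.98 ± 0.23, adjusted p = 0.00235) and the integrin gene Itga2b (-0.74 ± 0.20, adjusted p = 0.00723) were lower in KO mice in smoke at 24 weeks, and Pf4 was higher (0.53 ± 0.15, adjusted p = 0.0117). In air Itga2b stood at -1.04 ± 0.22, adjusted p = 0.00107.

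Single libraries at 24 weeks stood apart in some genes. Of KO mice in air, replicates 3, 4 and 7 held Cyp1a1 at 233, 113 and 104 CPM, Nqo1 at 26.6, 29.6 and 19.5 CPM, and Slc7a11 at 35.2, 19.7 and 32.8 CPM, with Awat1 at or under 0.06 CPM in each. KO CS replicate 8 held Cyp1a1 at 142, Nqo1 at 20.8 and Awat1 at 0.0922 CPM, and WT air replicates 1, 2, 3 and 5 held Cyp1a1 at 19.2 to 46.8 CPM. KO air replicate 2 held the mucous cell genes Clca1 at 588, Muc5ac at 33.1 and Agr2 at 5.56 CPM. Ceacam2 had means of 2.64 ± 3.55 and 0.112 ± 0.0784 CPM in WT and KO mice in air at 4 weeks, and of 0.0946 ± 0.0859 and 1.78 ± 3.15 CPM at 24 weeks. No explanation was tested. For KO air replicates 3, 4 and 7 smoke, another AhR ligand or a wrong label stays open. Dbp (5.49, 11.3 and 7.71 CPM) and Hspa1b (291, 83.1 and 149 CPM) argue against a swap with KO CS (15.3 to 115 and 2.92 to 28.0 CPM).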
